A study of Mus musculus with 7 samples.

How the data were processed

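The data were 7 single cell RNA libraries of CD31 captured cells from 1 brain hemisphere of untreated C57Bl6 mice, 3 from mice aged 12 months and 4 from mice aged 3 months. The deposited matrices hold raw UMI counts per gene and cell barcode, and per the file headers the authors made them with Cell Ranger 4.0.0 for the 12-month and 6.1.1 for the 3-month libraries. The submitters' processing notes name Cell Ranger, the build mm10 (GRCm38) and Seurat, and settings are not given in the sources used here. Whether intronic reads were counted and how barcodes were called as cells is not given in the sources used here. From the values, the lowest total per barcode was 500 or 501 UMIs in each file. The files of 3-month libraries list 1 more feature, a yellow fluorescent protein, which held 0 UMIs and was left out. The 32285 genes shared by all files were kept, and 78 symbols stand on more than 1 line and were told apart by gene ID. Coordinates came from the GENCODE annotation of GRCm38, which held 32235 of these gene IDs (99.85%). Near-identical paralogs share reads, and those named here are called uncertain. Some genes that the naming rule took are not reported here.

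Total UMIs were 8706961, 25493316 and 24035485 in 12-month replicates 1 to 3 and 20041722, 34372533, 44861008 and 29721428 in 3-month replicates 1 to 4. Barcodes numbered 6697, 6672 and 10213 against 4435, 4589, 6436 and 4049. Barcodes with fewer than 500 genes or more than 15% mitochondrial UMIs were removed, and so were the 0.8% per 1000 barcodes with the highest doublet scores of scrublet (scanpy 1.11.5). In 12-month replicate 1, 1366 barcodes fell under 500 genes, against 112 to 499 in the other 6 libraries. Median genes per cell were 715, 1370 and 1000 against 1552, 2161, 2043 and 2204, and median mitochondrial shares 1.93%, 4.98% and 4.08% against 2.02%, 3.79%, 3.67% and 3.29%. Shares of single libraries carry 95% exact Clopper-Pearson intervals, which cover counting error only.

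Cells were clustered with Seurat 5.3.0 in R 4.3.3: log normalization, 2000 variable features, 30 principal components, RPCA integration over libraries and Louvain clustering at resolution 0.5. Endothelial cells were integrated and clustered again at 0.5. Genes of the readout lists, naming markers and sex-linked, ribosomal and mitochondrial genes were kept out of the variable features. Clusters were named from fixed markers. A cluster stayed unnamed where fewer than 3 of them were raised, 2 classes scored alike, its leading genes were not those of its class, or high UMIs met markers of 2 classes. Markers of other cell types were summed in CPM in each class and library. UMI counts were summed per library and class, and a class was used in a library where it held at least 20 cells.

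Shares were compared by a two-sided exact permutation test of the difference in means over the 35 splits of the libraries, with Benjamini-Hochberg adjustment over 13 classes. Genes were tested with edgeR 4.0.16 (TMM, filterByExpr, quasi-likelihood test, adjusted p under 0.05), by age alone in each of 7 classes, and between classes with the library as a term. The interaction test had terms for library, class and class by age. Calls between classes were counted among genes of the 26 fixed lists that had no part in clustering or naming. Lists with at least 5 members tested were compared with other genes by camera (limma 3.58.1, preset correlation 0.01), beside camera with an estimated correlation and fry, which tests whether a list's genes move one way on balance and does not compare the list with other genes. Pearson correlations between libraries ran over log2(CPM + 1) of the genes.

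Genes were named by a rule. For the ages they had to pass the test with no overlap of the ages, a mean of at least 50 CPM, and be no predicted, mitochondrial, ribosomal or sex-linked gene. Of these, the 10 with the highest and the 10 with the lowest log2 fold change were taken in capillary cells and pericytes and 5 and 5 in other classes, plus up to 4 members of each list past the threshold with the smallest p. Between classes, up to 4 members of each list past the threshold with at least 50 CPM and the largest change were taken, and for the interaction the 5 highest and 5 lowest. Sex-linked genes and cluster genes outside this rule were chosen after their values were seen, and clock genes outside it after those of Dbp, Nr1d1 and Nr1d2 and before their own. Lists, markers, tests, the naming rule and the alternatives were fixed before the data were examined, except where a choice is said to be made after.

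Alternatives were leaving out each library, the replicate number as a block, size factors and the Wald test of DESeq2 1.42.0, no filter beyond 1 count, CPM of at least 50 in 3 libraries, sums thinned to the smallest, doublets kept, at least 1000 genes or at most 10% mitochondrial UMIs per cell, resolution 1.0, no integration, removal of sex-linked, mitochondrial and ribosomal genes, other pseudocounts and gene sets for correlations, and 1 age at a time between classes. Added after the data were seen were fits without the 2 libraries that hold Xist and without the low-UMI capillary cluster. The fits were tested on simulated data with changes of known size. False calls numbered 17 of 188 in capillary, 20 of 210 in arterial against capillary and 20 of 208 in venous against capillary sums, above the 5% aimed at, and 2 of 125 in pericytes. These ran on 12019, 9950, 10831 and 7960 genes. The age fits of arterial (10 of 156), venous (11 of 169) and microglia sums (11 of 155) also lay above 5%. So did DESeq2 in capillary sums (28 of 197). Of age changes of 1 in log2, 77% were found in capillary and 38% in pericyte sums, and of changes of 2, 94% and 85%. Pairs of libraries were checked for 1 library standing under 2 names, and none was found. B cells, T and NK cells, choroid plexus cells and unnamed clusters entered the shares only, since no gene test was planned for unnamed clusters and the others held too few cells in some libraries. Sex is not in the labels and was no term of any fit.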

Results

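The series holds 7 single cell RNA libraries of mouse brain microvessels. Each came from 1 cerebral hemisphere of an untreated C57Bl6 mouse, an inbred laboratory strain. The tissue was digested with collagenase, and cells were captured on beads carrying an antibody to CD31, the product of Pecam1, a surface protein of endothelial cells. The labels give 3 libraries from mice aged 12 months and 4 from mice aged 3 months. The libraries were made with a droplet method that tags each captured mRNA with a unique molecular identifier (UMI). Total UMIs ran from 8706961 (12-month replicate 1) to 44861008 (3-month replicate 3). After filtering, the 12-month libraries held 5006, 5993 and 8912 cells with medians of 1094, 2780 and 1808 UMIs per cell. The 3-month libraries held 3951, 3978, 5541 and 3795 cells with medians of 3073, 5328, 4558 and 4906 UMIs per cell. Per the labels and file headers, the 12-month libraries carry a single index and were counted with Cell Ranger 4.0.0, and the 3-month libraries carry a dual index and were counted with Cell Ranger 6.1.1. Age, library set and depth per cell therefore change together, and each value for 12 against 3 months is a difference between these library sets. Sex, as read below from Xist and Ddx3y, is not balanced between the ages either. The series describes a method to isolate the brain's microvessels, so the questions addressed here are which cells it yields, how their genes differ along the vessel tree, how alike replicates are, and how the ages differ.

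Clustering gave 22 clusters of all cells and, within the endothelial cells, 13. Marker genes named capillary, arterial and venous endothelial cells, pericytes (the mural cells wrapped around capillaries), smooth muscle cells of larger vessels, microglia (the brain's resident macrophages), erythroid cells, B cells, T and NK cells and choroid plexus epithelium, the tissue that makes cerebrospinal fluid. A cluster stayed unnamed where fewer than 3 markers were raised, 2 classes scored alike or its leading genes were not those of its class. Capillary cells filled 4 endothelial clusters of 8258, 6449, 4180 and 3686 cells. Of these, the cluster of 3686 cells had a median UMI count 0.643 times that of all endothelial cells and was led by Lars2, Ivns1abp, Ttr and Slc7a5. It held 47 of 5006, 224 of 5993 and 418 of 8912 cells at 12 months. At 3 months it held 640 of 3951, 647 of 3978, 1006 of 5541 and 704 of 3795. The cluster of 8258 cells was led by Car4, Mt1, Ankrd37 and Mt2 and held 903, 1294 and 2558 against 861, 782, 1121 and 739 cells.

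Endothelial cells made up 74.2% ± 3.26 against 83.8% ± 1.7 of the cells at 12 and 3 months (mean ± SD, n = 3 and n = 4). Capillary endothelial cells were the most numerous class in each library, at 53.1% ± 11.4 against 67.3% ± 0.781. The capillary share of single libraries, with its 95% exact binomial interval, was 40.1% (38.7 to 41.5) in 12-month replicate 1, 58.3% (57 to 59.6) in replicate 2 and 61.0% (60 to 62) in replicate 3. In the 3-month libraries it was 66.5% (65 to 68), 66.8% (65.3 to 68.3), 68.2% (67 to 69.4) and 67.7% (66.2 to 69.2). Arterial cells took 9.64% ± 2.12 against 5.81% ± 0.812, venous cells 6.09% ± 2.3 against 5.41% ± 1.35, smooth muscle cells 3.54% ± 1.89 against 3.22% ± 0.873 and pericytes 2.66% ± 1.82 against 1.53% ± 0.514. Microglia took 10.5% ± 8.89 against 3.62% ± 1.09: 19.3% (18.2 to 20.4) in 12-month replicate 1, 1.5% (1.21 to 1.84) in replicate 2 and 10.8% (10.2 to 11.5) in replicate 3. A two-sided exact permutation test over the 35 splits of the 7 libraries gave p = 0.0286, the smallest it allows, for the capillary (difference -14.2 percentage points), arterial (3.84) and all-endothelial (-9.59) shares, and adjusted p = 0.124 over the 13 classes. None of the 13 shares therefore passed, and edgeR on the cell counts gave a smallest adjusted p of 0.0593. With so few shares at the smallest p, the adjusted permutation test could not pass any of them, however large the difference. Leaving out 12-month replicate 1 took the capillary difference to -7.64.

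**Figure D1:**
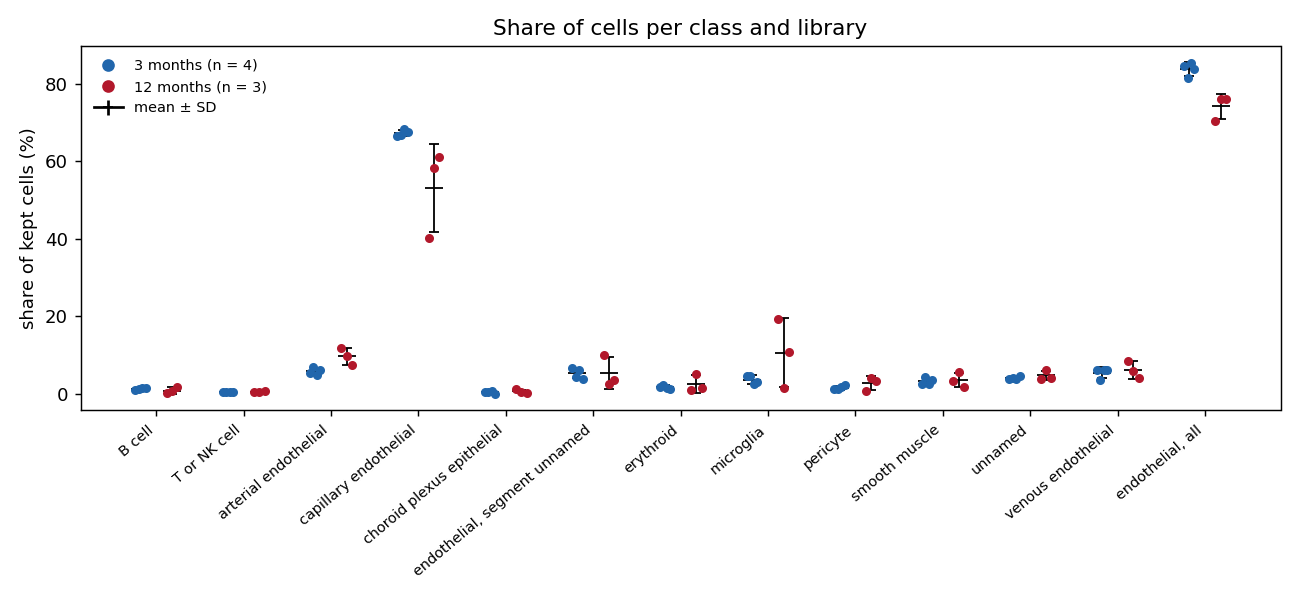
Share of the cells of each library (%, vertical axis) in each class (horizontal axis), with 1 point per library and bars of mean ± SD over the 3 libraries of 12-month and the 4 of 3-month mice. Capillary shares lie between 40.1% and 61.0% at 12 months and between 66.5% and 68.2% at 3 months.

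Summed expression of a class was alike between replicates where the class held many cells. Over all genes, the median Pearson correlation of log2(CPM + 1) between replicate libraries was 0.986 at 12 months (3 pairs) and 0.993 at 3 months (6 pairs) in capillary cells, and 0.987 between ages (12 pairs). CPM are the UMI counts of a class in a library scaled to a common total, so they give shares and not amounts per cell. In arterial cells it was 0.967 and 0.975, in venous cells 0.974 and 0.984, in smooth muscle 0.918 and 0.948, and in microglia 0.906 and 0.936. Pericytes, with 31 cells in 12-month replicate 1, gave 0.804 at 12 months (0.797 to 0.948) and 0.921 at 3 months. These correlations run across genes, which are not independent replicates, and no test was made on them.

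As shares of their UMIs, arterial endothelial cells held less of the transport genes of the blood-brain barrier than capillary cells of the same libraries, and more of the Notch ligands. Arterial cells held 2916 ± 1312 and 8514 ± 1918 UMIs per cell at 12 and 3 months, against 2110.5 ± 1030 and 5689 ± 1445 in capillary cells. A smaller share therefore need not mean fewer UMIs per cell. Values are log2 arterial over capillary ± SE and CPM as mean ± SD over n = 7 libraries. Among solute carriers of the barrier, 2 of 21 members were higher and 15 lower (2 and 15 adjusted over the list alone). The glutamate transporter Slc1a1 (-2.12 ± 0.11, 42.8 ± 12.6 against 190.2 ± 15.4 CPM) and the glutamine transporter Slc38a3 (-2.10 ± 0.09, 49.9 ± 16.1 against 216 ± 33.4 CPM) were lower. So was the iron exporter ferroportin, Slc40a1 (-1.92 ± 0.09, 118 ± 53.2 against 437 ± 145 CPM), at ENSMUSG00000025993, chromosome 1, 45908068 to 45926523. Of the ABC efflux transporters, pumps that return compounds to the blood, 1 of 10 members were higher and 5 lower (1 and 5 adjusted over the list alone). Lower ones were Abcg2 (-1.0 ± 0.09, 456 ± 63.5 against 927 ± 173 CPM) and Abcb1a (-0.54 ± 0.07, 1004 ± 294 against 1436 ± 264 CPM). Of receptors and vesicle transport genes, 5 of 14 members were higher and 8 lower (5 and 8 adjusted over the list alone), and Lrp8 (-1.43 ± 0.11, 63.9 ± 26.3 against 174 ± 29.3 CPM) was lower. Of Wnt and barrier regulators, 2 of 19 members were higher and 10 lower (3 and 11 adjusted over the list alone). Apcdd1 stood at -2.13 ± 0.12, Nkd1 at -1.97 ± 0.10 and Reck at 1.35 ± 0.10.

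The Notch ligands Jag1 (1.94 ± 0.09, 172 ± 20.4 against 44.1 ± 11.3 CPM) and Jag2 (1.38 ± 0.08, 408 ± 69.6 against 156 ± 16.7 CPM) were higher in arterial cells. Dll4 (1.30 ± 0.09) and the receptor Notch4 (1.05 ± 0.09) were higher too. In their list of VEGF, angiopoietin and Notch genes, 9 of 18 members were higher and 5 lower (9 and 6 adjusted over the list alone). Of TGF-beta and BMP genes, 11 of 22 members were higher and 6 lower (12 and 6 adjusted over the list alone). Smad6 (1.93 ± 0.07), an inhibitor of BMP signalling, Ltbp4 (1.30 ± 0.08) and Tgfb2 (1.14 ± 0.10) were higher. Edn1 (1.30 ± 0.09, 700.4 ± 148 against 286 ± 66.9 CPM), the gene of the vasoconstrictor endothelin-1, was higher. In its vasoactive list, 7 of 16 members were higher and 4 lower (9 and 5 adjusted over the list alone). Col18a1, the gene of basement membrane collagen XVIII, was higher by 4.76 ± 0.10 (162 ± 57 against 5.74 ± 1.44 CPM, ENSMUSG00000001435, chromosome 10, 77052178 to 77166548). Mylk, the gene of myosin light chain kinase, was higher by 3.16 ± 0.14. Beside them, smooth muscle markers summed to 127 ± 46.2 against 356 ± 481 CPM in arterial and 66.3 ± 40.8 against 26.5 ± 17.3 CPM in capillary sums at 12 and 3 months. Fibroblast markers summed to 41.9 ± 32.5 against 40.9 ± 14.1 CPM and 2.86 ± 1.55 against 3.02 ± 1.42 CPM. The metallothioneins Mt1 (-2.86 ± 0.20, 151 ± 96.3 against 1063 ± 299 CPM) and Mt2 (-3.07 ± 0.19) were lower. Of MHC class I genes, 12 of 14 members were higher and 1 lower (12 and 1 adjusted over the list alone). Of mitochondrially encoded genes, 0 of 13 members were higher and 13 lower (0 and 13 adjusted over the list alone). In edgeR with a library term, 255 of 496 listed genes differed, 138 higher and 117 lower. Of the 86 named genes, 82 kept their call in each leave-one-out fit and 56 in each of the other settings.

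As shares of their UMIs, venous endothelial cells held more of leukocyte adhesion, MHC class I and immediate early genes than capillary cells, and less of basement membrane and transport genes (log2 venous over capillary ± SE, n = 7). Venous cells held 5435 ± 3086 and 16179 ± 3774 UMIs per cell at 12 and 3 months, against 2110.5 ± 1030 and 5689 ± 1445 in capillary cells. A smaller share therefore need not mean fewer UMIs per cell. Of leukocyte adhesion and NF-kB genes, 11 of 12 members were higher and 0 lower (11 and 0 adjusted over the list alone). They included Lrg1 (5.73 ± 0.31, 337 ± 259.6 against 11.6 ± 18 CPM) and the cholesterol hydroxylase Ch25h (4.01 ± 0.20, 176 ± 48.9 against 14.4 ± 13.5 CPM). Icam1 (1.72 ± 0.18, 549 ± 505 against 169 ± 156 CPM), an adhesion receptor for leukocytes, was higher. Of MHC class I genes, 14 of 14 members were higher and 0 lower (14 and 0 adjusted over the list alone), with H2-K1 (0.77 ± 0.07, 1702 ± 241 against 1059 ± 354 CPM). H2-Q6 (2.06 ± 0.18) and H2-Q7 (1.86 ± 0.17) are near-identical paralogs, and which of them was counted is uncertain. Among immediate early genes, induced soon after a stimulus in many cell types, 17 of 22 members were higher and 0 lower (20 and 0 adjusted over the list alone). Socs3 (2.10 ± 0.09, 364 ± 243 against 94.1 ± 71.1 CPM), an inhibitor of cytokine signalling, Ier3 (1.58 ± 0.10) and Zfp36 (1.21 ± 0.08) were higher. Of cytosolic ribosomal protein genes, 83 of 84 members were higher and 0 lower (83 and 0 adjusted over the list alone). Of basement membrane genes, 0 of 15 members were higher and 14 lower (0 and 14 adjusted over the list alone). The collagen IV chains Col4a1 (-0.76 ± 0.05, 269 ± 47.7 against 475 ± 112 CPM) and Col4a2 (-0.89 ± 0.07, 159 ± 28.3 against 311 ± 87 CPM) were lower. The perlecan gene Hspg2 was lower by -0.97 ± 0.10.

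Solute carriers were lower in venous cells too: 4 of 21 members were higher and 12 lower (4 and 12 adjusted over the list alone). Slco1c1 (-1.95 ± 0.08, 350.4 ± 97.8 against 1371 ± 294 CPM), a thyroid hormone transporter at ENSMUSG00000030235, chromosome 6, 141524368 to 141570177, was lower. Slc1a1 (-2.53 ± 0.11) and Slc7a1 (-1.41 ± 0.07) were lower. Of receptors and vesicle transport genes, 3 of 14 members were higher and 10 lower (3 and 10 adjusted over the list alone). Of Wnt and barrier regulators, 3 of 19 members were higher and 13 lower (3 and 13 adjusted over the list alone). The Wnt targets Axin2 (-1.05 ± 0.07) and Apcdd1 (-1.26 ± 0.12) were lower. Nrp2 (2.59 ± 0.09, 479 ± 74.9 against 82.9 ± 15.3 CPM), a neuropilin co-receptor for VEGF and semaphorins at ENSMUSG00000025969, chromosome 1, 62703285 to 62818695, was higher. Its relative Nrp1 (-0.94 ± 0.09) and Jag2 (-1.02 ± 0.09) were lower, in a list where 4 of 18 members were higher and 9 lower (4 and 9 adjusted over the list alone). The ferritin heavy chain Fth1 (2.04 ± 0.09, 7764 ± 2499 against 1924 ± 551 CPM) and the lipid carrier Apoe (1.11 ± 0.09, 1874 ± 483 against 885 ± 105.2 CPM) were higher. Of interferon response genes, 3 of 26 members were higher and 14 lower (3 and 14 adjusted over the list alone). The test called 336 of 496 listed genes, 223 higher and 113 lower. Of the 82 named genes, 79 kept their call in each leave-one-out fit and 53 in each of the other settings.

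**Figure D2:**
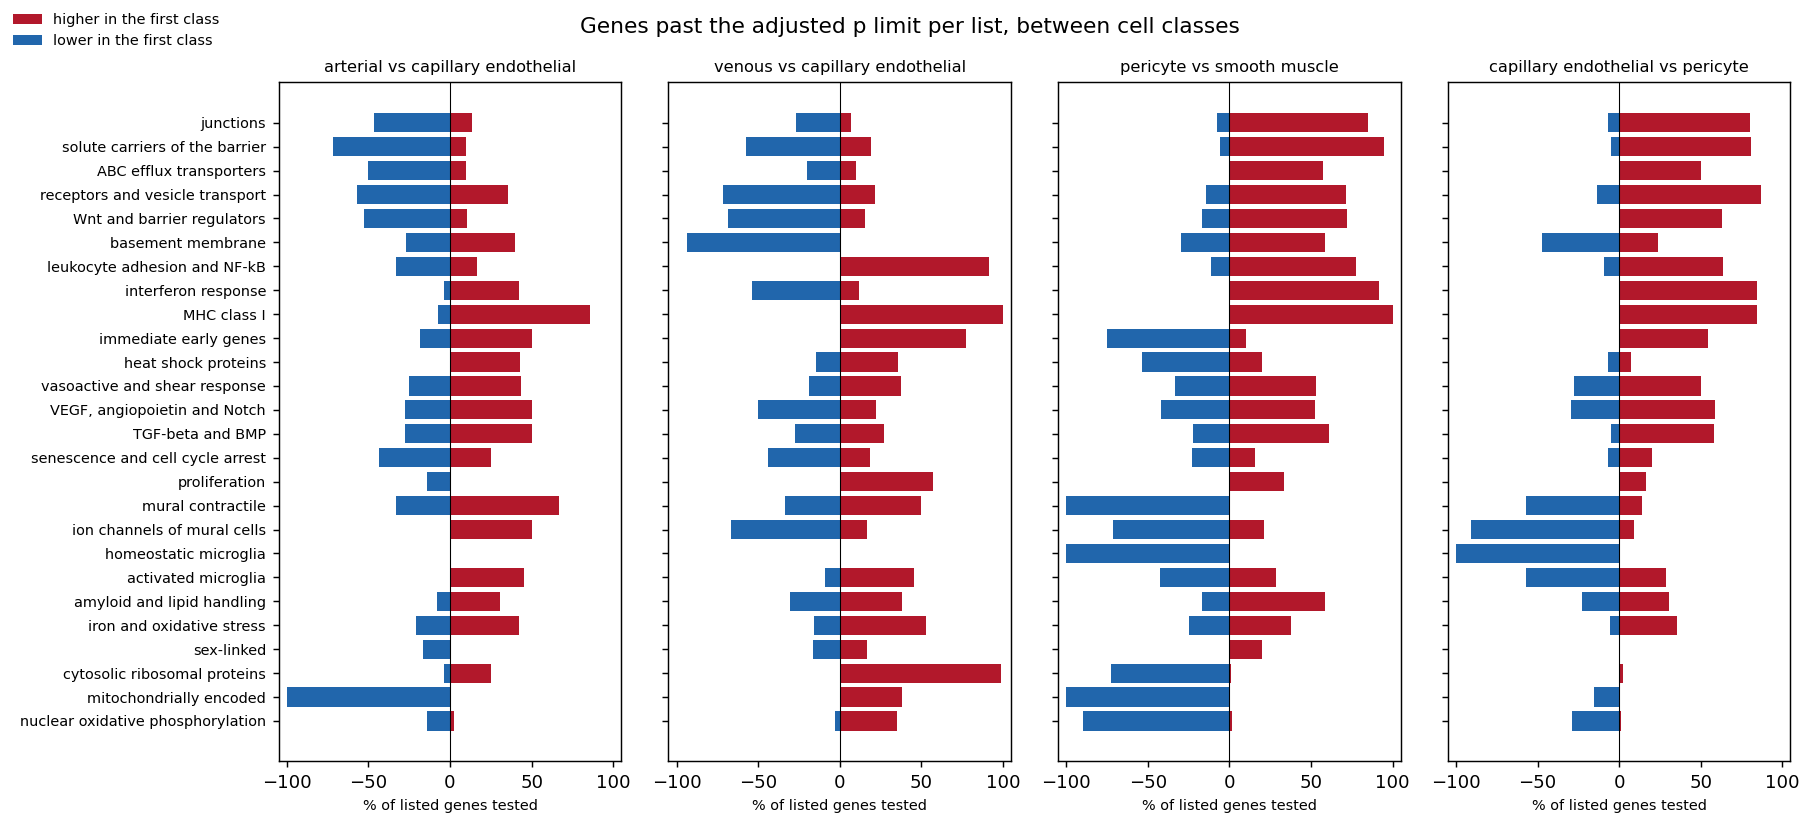
Members of each gene list (vertical axis) past the threshold, as a percentage of those tested (horizontal axis), in the 4 comparisons between cell classes over 7 libraries, with members higher in the class named first to the right (red) and those lower in it to the left (blue). In venous against capillary cells, 83 of 84 ribosomal protein genes were higher and 14 of 15 basement membrane genes lower.

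Pericytes and smooth muscle cells, the mural cells of the vessel wall, differed in genes of contraction (log2 pericyte over smooth muscle ± SE, n = 7). Of mural contractile genes, 0 of 8 members were higher and 8 lower (0 and 8 adjusted over the list alone). They included the filamin gene Flna (-3.96 ± 0.13, 145 ± 40 against 1856 ± 130.5 CPM) and Mylk (-3.75 ± 0.12, 234 ± 72.6 against 2536 ± 478 CPM). The tropomyosin gene Tpm1 (-3.89 ± 0.12, 366 ± 64.6 against 4632 ± 1106 CPM) lies at ENSMUSG00000032366, chromosome 9, 67022590 to 67049406. Of ion channels of mural cells, 3 of 14 members were higher and 10 lower (3 and 10 adjusted over the list alone). The potassium channel Kcnk3 (-3.02 ± 0.18) and the calcium pump Atp2a2 (-2.61 ± 0.11) were lower in pericytes. The phosphodiesterase Pde3a (-4.39 ± 0.15, 34.2 ± 11.2 against 589 ± 159.6 CPM) was lower, as were the prostacyclin synthase Ptgis (-4.63 ± 0.21), Col18a1 (-5.46 ± 0.23) and Ltbp1 (-5.49 ± 0.20). The laminin chain Lama2 was higher by 2.32 ± 0.17. Among immediate early genes, 2 of 20 members were higher and 15 lower (2 and 15 adjusted over the list alone), and Fos (-2.38 ± 0.14, 1258 ± 629.7 against 5174 ± 2155 CPM) was lower. Of nuclear genes of oxidative phosphorylation, 1 of 77 members were higher and 69 lower (1 and 69 adjusted over the list alone). Of mitochondrially encoded genes, 0 of 13 members were higher and 13 lower (0 and 13 adjusted over the list alone). Solute carriers were higher in pericyte sums, where 17 of 18 members were higher and 1 lower (17 and 1 adjusted over the list alone). So were junction genes, where 11 of 13 members were higher and 1 lower (11 and 1 adjusted over the list alone). Among MHC class I genes, 12 of 12 members were higher and 0 lower (12 and 0 adjusted over the list alone). Summed endothelial markers were also higher in pericyte sums, at 13573 ± 2564 against 18340 ± 800.4 CPM at 12 and 3 months, than in smooth muscle sums, at 1808 ± 249 against 832 ± 286 CPM. The test called 388 of 468 listed genes, 162 higher and 226 lower. Of the 91 named genes, 90 kept their call in each leave-one-out fit.

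Pericytes also differed from capillary endothelial cells in genes of mural cell signalling (log2 capillary over pericyte ± SE, n = 7). Of ion channels of mural cells, 1 of 11 members were higher and 10 lower (1 and 10 adjusted over the list alone). The chloride channel Ano1 (-8.02 ± 0.17, 0.463 ± 0.247 against 127 ± 56.7 CPM) was lower in capillary cells. Both subunits of the nitric oxide receptor were lower, Gucy1b1 (-8.30 ± 0.18, 1.06 ± 0.695 against 406 ± 122 CPM) and Gucy1a1 (-7.98 ± 0.18). The receptor Notch3 (-7.66 ± 0.15, 1.62 ± 0.808 against 335 ± 129 CPM), at ENSMUSG00000038146, chromosome 17, 32120820 to 32166852, and its target Heyl (-7.76 ± 0.22) were lower. Cox4i2 (-8.43 ± 0.16, 1.08 ± 0.488 against 417 ± 137 CPM), a respiratory chain subunit, was lower, as were the lipoprotein receptor Lrp1 (-6.26 ± 0.16) and Lama2 (-8.72 ± 0.22). Of basement membrane genes, 4 of 17 members were higher and 8 lower (4 and 8 adjusted over the list alone). Of junction genes, 12 of 15 members were higher and 1 lower (12 and 1 adjusted over the list alone), and Jam2 stood at 0.89 ± 0.10. Of solute carriers, 17 of 21 members were higher and 1 lower (18 and 1 adjusted over the list alone). Endothelial markers summed to 27497 ± 1325 against 27240 ± 2018 CPM in capillary and 13573 ± 2564 against 18340 ± 800.4 CPM in pericyte sums at 12 and 3 months. Among interferon response genes, 22 of 26 members were higher and 0 lower (23 and 1 adjusted over the list alone). Among MHC class I genes, 11 of 13 members were higher and 0 lower (12 and 0 adjusted over the list alone). The test called 238 of 493 listed genes, 165 higher and 73 lower. Of the 84 named genes, 77 kept their call in each leave-one-out fit and 59 in each of the other settings. With clustering at resolution 1.0, Icam1, Csf1, Ifi27l2a, H2-Q7, Atf3, Jun and Cd9 turned from higher to lower in capillary cells, at -0.60, -0.30, -0.17, -0.39, -0.21, -0.0212 and -0.35, without a call. With no integration Cd9 (-1.05), Ifi27l2a (-0.43) and Jag2 (-0.40) were called lower in capillary cells.

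Between the ages, immediate early and NF-kB genes took a larger share of the UMIs in capillary endothelial cells of the 12-month libraries (log2 12 over 3 months ± SE, CPM as mean ± SD, n = 3 and n = 4). Per cell, UMIs of the immediate early genes were not more, at 52.1 ± 27.5 against 62.3 ± 18.7, since 12-month cells held fewer UMIs of all genes. Beside these groups, microglia markers summed to 173 ± 75.3 against 46.1 ± 9.72 CPM in capillary sums. Atf3 (3.60 ± 0.36, 909.5 ± 627 against 78.7 ± 10.5 CPM) encodes a stress-induced transcription factor (ENSMUSG00000026628, chromosome 1, 191170296 to 191218039). It stood at 1625, 650.1 and 453 CPM in the 12-month libraries and between 64.3 and 89.5 CPM in the 3-month libraries (adjusted p = 0.000267, higher in 3 of 3). The AP-1 subunits Fos (2.15 ± 0.20, 3429 ± 716 against 817 ± 100 CPM) and Fosb (2.39 ± 0.38, 1572 ± 302 against 313 ± 177 CPM) were higher. Fos lies at ENSMUSG00000021250, chromosome 12, 85473890 to 85477273. Jun (1.41 ± 0.18, 5279 ± 662 against 2107 ± 157 CPM), Egr1 (2.09 ± 0.32, 1522 ± 370.5 against 375 ± 155 CPM) and Socs3 (2.15 ± 0.18, 167 ± 35.9 against 39.7 ± 7.43 CPM) were higher as well. Of the immediate early genes, 14 of 23 rose (17 adjusted over the list alone, mean 1.20). The list gave adjusted p = 1.55e-29 by camera, adjusted p = 0.0576 with an estimated correlation. Of leukocyte adhesion and NF-kB genes, 9 of 18 rose (13 adjusted over the list alone, mean 1.96). This list gave adjusted p = 1.73e-12 by camera, adjusted p = 0.245 with an estimated correlation, and with no integration of libraries its call was lost (mean 0.40). Icam1 (2.20 ± 0.36, 301 ± 161 against 69.1 ± 25.7 CPM) and Nfkbiz (2.29 ± 0.33, 139.6 ± 54.3 against 29.9 ± 12.9 CPM), an inducible IkB protein, were higher. Lcn2 (3.76 ± 0.55, 78.6 ± 55.2 against 6.1 ± 2.38 CPM), the iron-binding protein lipocalin 2, was higher. So were Ptgs2 (2.80 ± 0.37, 104 ± 66.1 against 15.7 ± 4.01 CPM), the inducible cyclooxygenase, and Klf4 (1.47 ± 0.23, 1937 ± 323 against 743 ± 193 CPM), a factor that shear stress induces.

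Genes lower in 12-month capillary cells included Dbp and Nr1d1 of the circadian clock and the transporter gene Slc7a5. Dbp (-2.46 ± 0.33, 13.4 ± 3.88 against 82.6 ± 32.6 CPM), a clock output factor, fell in 3 of 3 libraries (adjusted p = 0.00153). It lies at ENSMUSG00000059824, chromosome 7, 45705088 to 45710203. Nr1d1 (-1.11 ± 0.19, 46.4 ± 5.4 against 107 ± 19.8 CPM), the clock repressor REV-ERB alpha, was lower too (ENSMUSG00000020889, chromosome 11, 98767932 to 98775333). Of other clock genes, Tef at -1.05 and Nr1d2 at -0.85 were called lower. Nfil3 at 2.41, Usp2 at 1.70, Npas2 at 1.45 and Arntl at 0.75 were called higher. Slc7a5 (-1.31 ± 0.19, 268 ± 29.7 against 705 ± 107 CPM), a subunit of the large neutral amino acid transporter, was lower (ENSMUSG00000040010, chromosome 8, 121881150 to 121907694), and so was Ivns1abp (-1.44 ± 0.19, 63.1 ± 15.2 against 184 ± 20.3 CPM). Both genes lead the low-UMI capillary cluster, which held more 3-month cells, and without it they stood at -1.19 and -1.09. Of solute carriers of the barrier, 2 of 26 fell (3 adjusted over the list alone). The list gave adjusted p = 0.0013 by camera, adjusted p = 0.635 with an estimated correlation, and without 12-month replicate 1 its call was lost (mean -0.13). The apelin receptor gene Aplnr (-3.44 ± 0.53, 1.45 ± 1.28 against 12.1 ± 6.47 CPM) was lower. Nrep (-1.47 ± 0.22), a neuronal regeneration gene, and Fam13a (-0.89 ± 0.15) were lower. Slc40a1 (-0.78 ± 0.18, 297 ± 49.4 against 543 ± 77.8 CPM) and the cholesterol exporter Abca1 (-0.91 ± 0.22) kept their calls in 2 of 7 and 2 of 7 leave-one-out fits, and lost them without the low-UMI cluster (-0.74 and -0.81). ABC efflux transporters did not pass as a list (2 of 10 lower, adjusted p = 0.0538 by camera).

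Of heat shock protein genes, 3 of 15 rose in capillary cells (6 adjusted over the list alone). Their list gave adjusted p = 4.62e-05 by camera, adjusted p = 0.528 with an estimated correlation. The co-chaperone Dnajb1 (1.20 ± 0.17, 142 ± 40.3 against 65.3 ± 2.71 CPM) was higher. Ankrd37 (1.94 ± 0.21, 187 ± 44.5 against 52.4 ± 13 CPM), a hypoxia-induced gene, was higher, and it is among the genes that lead the capillary cluster of 8258 cells. The cell cycle inhibitor Cdkn1a (1.63 ± 0.31) and the tubulin-binding Stmn2 (1.72 ± 0.28) were higher. Genes of microglia were higher in capillary sums. Of homeostatic microglia genes, 6 of 9 rose (8 adjusted over the list alone, adjusted p = 1.80e-14 by camera, adjusted p = 0.159 with an estimated correlation). Of activated microglia genes, 6 of 12 rose (10 adjusted over the list alone, adjusted p = 1.53e-14 by camera, adjusted p = 0.149 with an estimated correlation). Tmem119 stood at 2.93 ± 0.45 (4.72 ± 2.4 against 0.635 ± 0.357 CPM) and Ccl4 at 5.01 ± 0.61 (31 ± 22.7 against 0.921 ± 0.534 CPM). Summed microglia markers were 173 ± 75.3 against 46.1 ± 9.72 CPM in capillary sums. Ribosomal protein genes (0 of 85 members higher) and mitochondrially encoded genes (0 of 13) were called Up as lists, each with adjusted p = 0.635 with an estimated correlation. Basement membrane genes (0 of 15 lower, 5 adjusted over the list alone) were called Down as a list, adjusted p = 0.528 with an estimated correlation. In edgeR, 510 of 12172 genes differed, 346 higher and 164 lower. The 2 ages did not overlap in 19.0% of genes, where chance gives 5.71%. Of the named genes, 32 of the 51 kept their call in each leave-one-out fit and 18 in each of the other settings. The count was 291 without 12-month replicate 2, 882 without 3-month replicate 1, 281 without 3-month replicate 3, 278 without 3-month replicate 4. It was 356 without the low-UMI capillary cluster, a choice made after the data were seen, and 56 in sums thinned to the smallest library.

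**Figure D3:**
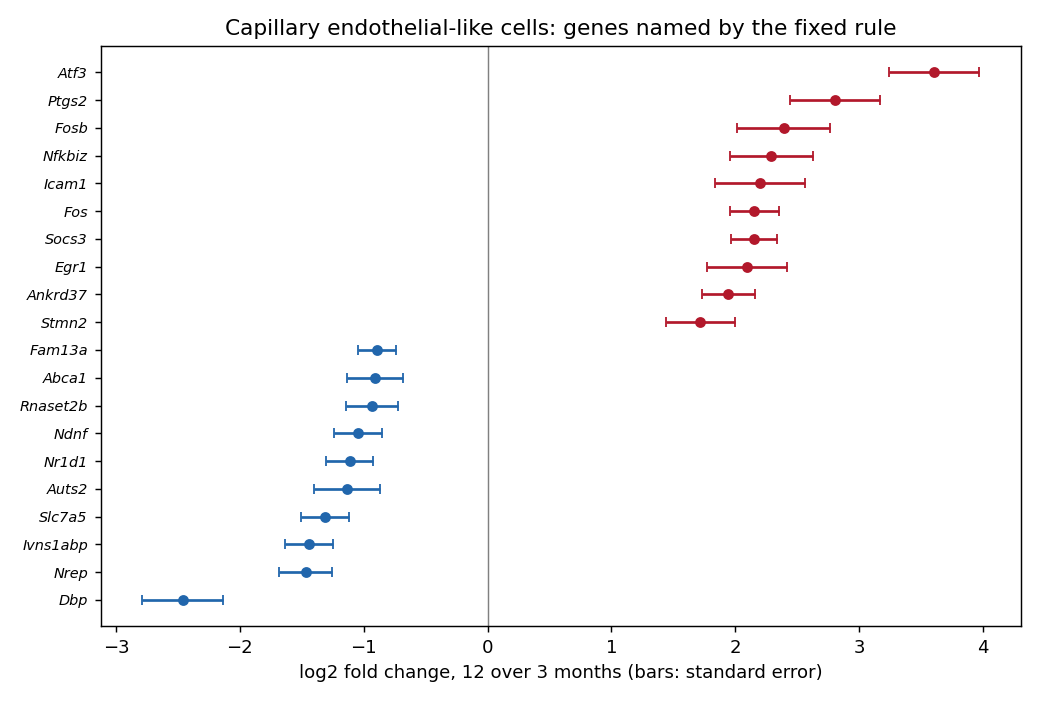
Log2 fold change, 12 over 3 months, in capillary endothelial cells (horizontal axis) of the 10 genes with the highest and the 10 with the lowest values by the naming rule (vertical axis), with points for edgeR estimates from 3 libraries of 12-month and 4 of 3-month mice and bars for ± SE. Atf3 lies at 3.60 ± 0.36 and Dbp at -2.46 ± 0.33.

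In arterial endothelial cells, Atf3 (2.59 ± 0.32, 746 ± 398 against 125 ± 29.1 CPM) and Socs3 (2.04 ± 0.22, 218 ± 27.6 against 54 ± 10.9 CPM) were higher at 12 months (n = 3 and n = 4). Fosb (1.90 ± 0.37, 1089 ± 98.2 against 299 ± 179 CPM) was higher, with its call kept in 2 of 7 leave-one-out fits (range 1.67 to 2.33). Dbp (-2.44 ± 0.34, 19.6 ± 4.04 against 112 ± 41.4 CPM) was lower, with its call lost without 12-month replicate 1. Of immediate early genes, 4 of 22 rose (12 adjusted over the list alone, adjusted p = 1.38e-18 by camera, adjusted p = 0.0133 with an estimated correlation). Heat shock genes were called Up as a list (1 of 15, 1 adjusted over the list alone, adjusted p = 1.50e-06 by camera, adjusted p = 0.581 with an estimated correlation). Solute carriers were called Down as one (mean -0.44, 1 member adjusted over the list alone, adjusted p = 8.72e-06 by camera, adjusted p = 0.581 with an estimated correlation). That call was lost without 12-month replicate 1 (mean -0.25) and turned to 0.18 with no integration. Emp1, a membrane protein gene, was higher (1.89 ± 0.32, kept in 3 of 7 leave-one-out fits). Microglia markers summed to 176 ± 90.6 against 48.5 ± 6.4 CPM. The test called 38 of 10169 genes, 32 higher and 6 lower, and 2 of the 12 named genes, Atf3 and Socs3, kept their call in each leave-one-out fit. The count was 16 without 12-month replicate 1, 21 without 12-month replicate 2, 24 without 12-month replicate 3, 102 without 3-month replicate 1, 14 without 3-month replicate 3, 13 without 3-month replicate 4.

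Leukocyte adhesion and NF-kB genes took a larger share of the UMIs in venous endothelial cells of the 12-month libraries (n = 3 and n = 4). The neutrophil chemokine Cxcl2 (5.93 ± 0.65, 139 ± 80.3 against 2.91 ± 3.1 CPM) and Icam1 (2.42 ± 0.32, 1009.5 ± 445 against 203 ± 80.1 CPM) were higher. So were E-selectin, Sele (5.52 ± 0.58, 125 ± 113 against 3.18 ± 2.34 CPM), and P-selectin, Selp (5.14 ± 0.61, 103 ± 92.4 against 3.63 ± 2.51 CPM). Sele lies at ENSMUSG00000026582, chromosome 1, 164048234 to 164057677. Of leukocyte adhesion and NF-kB genes, 10 of 18 rose (11 adjusted over the list alone, mean 1.54, adjusted p = 4.27e-19 by camera, adjusted p = 0.0921 with an estimated correlation). Of immediate early genes, 10 of 22 rose (17 adjusted over the list alone, adjusted p = 6.61e-35 by camera, adjusted p = 0.0335 with an estimated correlation). Atf3 (3.70 ± 0.25, 1338 ± 374 against 110 ± 16.4 CPM), Fosb (2.63 ± 0.37) and Gadd45b (2.47 ± 0.23) were higher. Rnd1 (3.63 ± 0.38), Clu (2.48 ± 0.26), the chaperone clusterin, and Dnajb1 (1.46 ± 0.20) were higher. Heat shock genes were called Up as a list (2 of 14, 5 adjusted over the list alone, adjusted p = 1.84e-06 by camera, adjusted p = 0.283 with an estimated correlation). Aplnr (-1.60 ± 0.26, 19 ± 5.95 against 61.6 ± 17.7 CPM) was lower, with its call lost without 12-month replicate 2 (range -1.90 to -1.39). Tril (-1.36), Pomc (-1.14) and Arl4a (-0.93) were lower, with calls kept in 5 of 7, 4 of 7 and 2 of 7 leave-one-out fits. Microglia markers summed to 110.4 ± 46 against 39.7 ± 7.47 CPM. The test called 252 of 10321 genes, 209 higher and 43 lower, and 16 of the 27 named genes kept their call in each leave-one-out fit. The count was 85 without 12-month replicate 2, 424 without 3-month replicate 1, 135 without 3-month replicate 3, 161 without 3-month replicate 4.

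Pericyte sums of the 12-month libraries held a larger share of Atf3 (2.35 ± 0.26, 303 ± 89.4 against 53.6 ± 16.3 CPM), Fosb (2.14 ± 0.28, 1057 ± 40.2 against 238 ± 113 CPM) and Ankrd37 (1.75 ± 0.26, 92.1 ± 13.3 against 30.6 ± 6.23 CPM) (n = 3 and n = 4). These 3 of the 27 named genes kept their call in each leave-one-out fit, and 2 of the 27 did in each of the other settings. All 3 genes were called higher in capillary cells too. Endothelial markers stood at 13573 ± 2564 against 18340 ± 800.4 CPM in pericyte and 27497 ± 1325 against 27240 ± 2018 CPM in capillary sums. A rise in the pericytes themselves was not told apart from one in that endothelial RNA. Ion channels of mural cells were called Up as a list (3 of 13, 9 adjusted over the list alone, mean 0.88, adjusted p = 5.44e-11 by camera, adjusted p = 0.277 with an estimated correlation). Abcc9 (1.34 ± 0.28, 1057 ± 263 against 423 ± 161 CPM), a subunit of ATP-sensitive potassium channels, was higher (ENSMUSG00000030249, chromosome 6, 142587862 to 142702315). The calcium channels Cacna1h (1.71 ± 0.33) and Cacna1c (1.34 ± 0.30) were higher. Calls of these 3 were kept in 3 of 7, 4 of 7 and 3 of 7 leave-one-out fits. Beside this group, pericyte markers, Abcc9 among them, summed to 22020 ± 5811 against 13185 ± 1582 CPM and erythroid markers to 6671 ± 4829 against 2453 ± 3725 CPM. Of immediate early genes, 5 of 22 rose (6 adjusted over the list alone, adjusted p = 2.47e-06 by camera, adjusted p = 0.277 with an estimated correlation), beside microglia markers at 375 ± 379 against 72 ± 36 CPM. Of solute carriers, 2 of 25 fell (10 adjusted over the list alone, adjusted p = 5.31e-08 by camera, adjusted p = 0.277 with an estimated correlation). Slc7a5 (-1.64 ± 0.31, 160.2 ± 73 against 434 ± 139.7 CPM) and Slc40a1 (-1.15 ± 0.27) were lower, with calls kept in 4 of 7 and 1 of 7 leave-one-out fits. Beside them, endothelial markers summed to 13573 ± 2564 against 18340 ± 800.4 CPM. Cygb (1.49 ± 0.29), cytoglobin, Pla1a (1.46 ± 0.25) and Itgb5 (1.35 ± 0.25) were higher, with calls kept in 5 of 7, 6 of 7 and 5 of 7 fits. The mural contractile list was called Up (adjusted p = 0.0361 by camera, adjusted p = 0.358 with an estimated correlation) with a mean of -0.01 and a median of 0.43. The test called 85 of 8330 genes, 64 higher and 21 lower, on sums as small as 52143 UMIs. The count was 21 without 12-month replicate 2, 9 without 12-month replicate 3, 293 without 3-month replicate 1, 14 without 3-month replicate 3, 23 without 3-month replicate 4.

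In smooth muscle sums, Atf3 (2.51 ± 0.45, 1484 ± 1322 against 243 ± 139 CPM) was higher at 12 months (n = 3 and n = 4). Genes known from endothelial cells were higher: Cldn5 (1.23 ± 0.26, 361 ± 113 against 153 ± 46.4 CPM), a tight junction protein, Flt1 (1.34 ± 0.23), a VEGF receptor, and Adgrf5 (1.66 ± 0.27). Junction genes were called Up as a list (1 of 16, 8 adjusted over the list alone, adjusted p = 1.60e-08 by camera, adjusted p = 0.0959 with an estimated correlation). MHC class I genes were too (1 of 10, 3 adjusted over the list alone, adjusted p = 2.60e-06 by camera, adjusted p = 0.116 with an estimated correlation). So were vasoactive genes (2 of 13, 4 adjusted over the list alone, adjusted p = 1.64e-05 by camera, adjusted p = 0.0959 with an estimated correlation). Beside these groups, endothelial markers summed to 1808 ± 249 against 832 ± 286 CPM, smooth muscle markers to 44440 ± 4909 against 54122 ± 9063 CPM and microglia markers to 174 ± 102 against 39 ± 5.92 CPM. With doublets kept, Cldn5 stood at -0.0324, Flt1 at -0.00641 and the junction and MHC class I lists at 0.0105 and 0.13, without a call, and the test called 3 genes. Col3a1 (-1.50 ± 0.26, 33.5 ± 3.68 against 91.2 ± 19.3 CPM), a fibrillar collagen, and Ccn2 (-1.36 ± 0.25) were lower, beside fibroblast markers at 133 ± 25.2 against 299.6 ± 53 CPM. Hspa1b (-1.75 ± 0.24, 70.5 ± 6.57 against 231 ± 49 CPM) was lower, an inducible heat shock protein with the near-identical paralog Hspa1a, so that its assignment is uncertain. The test called 43 of 8391 genes, 37 higher and 6 lower. The count was 17 without 12-month replicate 1, 15 without 12-month replicate 2, 92 without 3-month replicate 1, 26 without 3-month replicate 2, 13 without 3-month replicate 4. Of the 17 named genes, 3 kept their call in each leave-one-out fit and 0 in each of the other settings. Atf3 lost its call without 12-month replicate 1 (lowest value 1.54).

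Leukocyte adhesion and NF-kB genes took a larger share of the UMIs in microglia of the 12-month libraries (n = 3 and n = 4). The CC chemokines Ccl3 (2.54 ± 0.29, 3009 ± 186 against 535 ± 226 CPM) and Ccl4 (1.85 ± 0.30, 5677 ± 566 against 1629.7 ± 755 CPM) were higher. Ccl3 lies at ENSMUSG00000000982, chromosome 11, 83647844 to 83649355. Cxcl10 (2.70 ± 0.52, 174 ± 57.1 against 29.2 ± 40.7 CPM), an interferon-induced chemokine, and Csf1 (2.15 ± 0.29, 81.4 ± 21.5 against 20 ± 7.88 CPM), a macrophage growth factor, were higher. Of leukocyte adhesion and NF-kB genes, 4 of 10 rose (6 adjusted over the list alone, adjusted p = 1.10e-11 by camera, adjusted p = 0.0291 with an estimated correlation, mean 0.93), a call lost in sums thinned to the smallest (mean 0.23). Nfkbiz (2.03 ± 0.23) and Nfkbia (1.52 ± 0.24) were among them. Of immediate early genes, 7 of 23 rose (13 adjusted over the list alone, adjusted p = 6.06e-20 by camera, adjusted p = 0.0747 with an estimated correlation). Atf3 (2.76 ± 0.39) and Maff (2.92 ± 0.41) were higher. Of MHC class I genes, 3 of 13 rose (5 adjusted over the list alone, adjusted p = 0.000618 by camera, adjusted p = 0.379 with an estimated correlation). Among them were the paralogs H2-Q6 (2.43 ± 0.42) and H2-Q7 (2.03 ± 0.39), whose assignment is uncertain. Activated microglia genes were called Up as a list (2 of 11, 3 adjusted over the list alone, adjusted p = 2.45e-05 by camera, adjusted p = 0.261 with an estimated correlation). Homeostatic ones were called Down as one (mean -0.31, 1 member adjusted over the list alone, adjusted p = 0.00517 by camera, adjusted p = 0.379 with an estimated correlation), a call lost without 12-month replicate 1 (mean -0.19). Beside these lists, microglia markers summed to 33020 ± 1477 against 39358 ± 3549.7 CPM and endothelial markers to 1079 ± 804 against 554 ± 142 CPM. Hspa1b (-2.09 ± 0.32, 159 ± 77.3 against 735 ± 300.5 CPM) and Rsrp1 (-1.33 ± 0.22) were lower. So were the paralogs Rnaset2a (-1.46 ± 0.24) and Rnaset2b (-1.53 ± 0.22), again of uncertain assignment. The test called 108 of 6951 genes, 88 higher and 20 lower, and 70 without 3-month replicate 3. Of the named genes, 18 of the 26 kept their call in each leave-one-out fit and 3 in each of the other settings. Microglia numbered 965, 90 and 963 cells in the 12-month and 178, 182, 135 and 112 in the 3-month libraries.

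In the erythroid class, Atf3 (3.22 ± 0.30, 758 ± 324 against 88.4 ± 41.1 CPM) and Icam1 (2.62 ± 0.25, 338 ± 28.4 against 61.8 ± 24.5 CPM) were higher at 12 months (n = 3 and n = 4). Nfkbiz (2.64 ± 0.28, 169 ± 40.3 against 28.7 ± 14.7 CPM) and Fosb (2.50 ± 0.27, 1354 ± 17.9 against 270.1 ± 124 CPM) were higher. Of immediate early genes, 7 of 22 rose (17 adjusted over the list alone, adjusted p = 2.98e-39 by camera, adjusted p = 0.00157 with an estimated correlation). Of leukocyte adhesion and NF-kB genes, 7 of 18 rose (11 adjusted over the list alone, adjusted p = 8.88e-28 by camera, adjusted p = 0.0224 with an estimated correlation). Beside these groups, erythroid sums held endothelial markers at 17307 ± 1256 against 19688 ± 3226 CPM and microglia markers at 201 ± 138 against 30.1 ± 9.96 CPM. Erythroid markers took 277330 ± 21816 against 245800 ± 109810 CPM of these sums. In capillary sums endothelial markers stood at 27497 ± 1325 against 27240 ± 2018 CPM. The calls of the erythroid class were therefore not told apart from those of endothelial RNA within it. Of the named genes, 10 of the 19 kept their call in each leave-one-out fit and 4 in each of the other settings. The test called 61 of 7161 genes, 55 higher and 6 lower, and 38 without 12-month replicate 2, 143 without 3-month replicate 1, 37 without 3-month replicate 3. Over the 7 classes, 5 list calls held with an estimated correlation and 69 did not. Those that held were immediate early genes in the arterial, venous and erythroid classes, and leukocyte adhesion and NF-kB genes in microglia and the erythroid class. Some genes named for the ages also served to name clusters: Stmn2 and Clu (arterial), Lcn2 and Selp (venous), Slc7a5 (capillary), Cldn5 and Flt1 (endothelial), Abcc9 (pericyte) and Col3a1 (fibroblast).

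**Figure D4:**
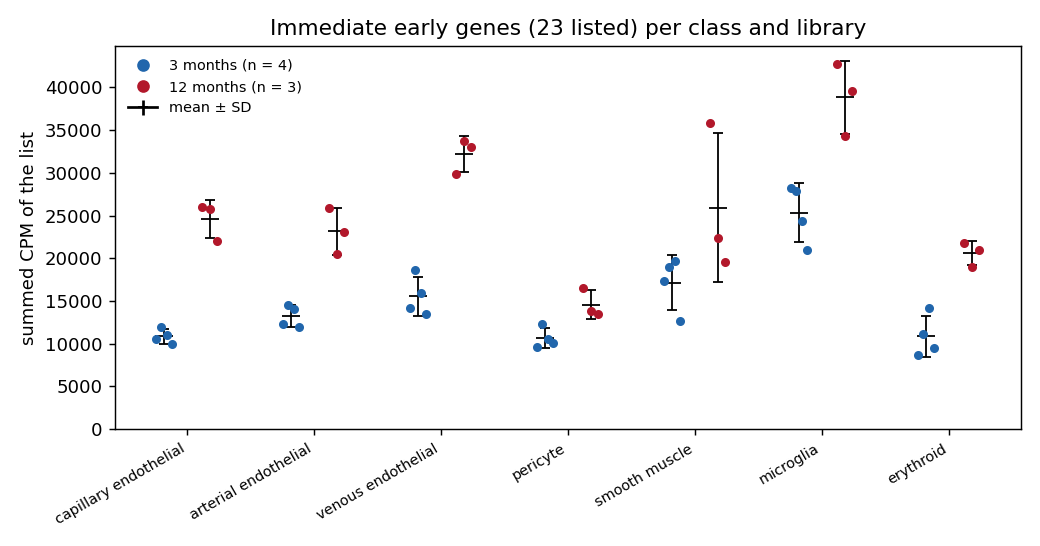
Summed expression of the immediate early genes (CPM, vertical axis) in each class (horizontal axis), with 1 point per library and bars of mean ± SD over the 3 libraries of 12-month and the 4 of 3-month mice. The means are 24604 ± 2192 against 10868 ± 848 CPM in capillary and 14578 ± 1666 against 10626 ± 1164 CPM in pericyte sums at 12 and 3 months.

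Whether the age difference itself differed between pericytes and capillary cells was tested with an interaction term (edgeR, n = 7 libraries, log2 of the pericyte age fold over the capillary one ± SE). Immediate early genes had a lower age fold in pericytes for 14 of 22 members, such as the AP-1 subunit Junb (-1.29 ± 0.14, 2334 ± 329 against 1016 ± 214 CPM in capillary and 1039 ± 219 against 1039 ± 127 CPM in pericyte sums). Another was Ier3 (-1.31 ± 0.16, 954 ± 263 against 419 ± 83.2 CPM in capillary and 384 ± 26.9 against 435 ± 88.1 CPM in pericyte sums). Ribosomal protein genes (57 of 84), solute carriers (5 of 26) and NF-kB genes (5 of 16) also held members lower by it. Itga4, an integrin subunit, was higher by 2.35 ± 0.25 (3.22 ± 1.01 against 19.4 ± 2.09 CPM in capillary and 112 ± 24.6 against 109 ± 30.1 CPM in pericyte sums, ENSMUSG00000027009, chromosome 2, 79255426 to 79333123). Tfpi, an inhibitor of coagulation, was higher by 1.26 ± 0.20 (24.6 ± 3.27 against 40.8 ± 0.96 CPM in capillary and 126 ± 32.1 against 86.1 ± 15.7 CPM in pericyte sums) and turned to -0.71 in thinned sums, without a call. The test called 362 of 10575 genes (106 higher, 256 lower in pericytes), 196 without 12-month replicate 3 and 164 without 3-month replicates 1 and 2. In sums thinned to the smallest library edgeR called 0 genes (286 at an unadjusted p under 0.05). Summed pericyte and endothelial markers in the pericyte sums differ between ages as given above.

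The labels do not give the sex of the mice. Xist, the X inactivation RNA, stood at 643.9 and 931.3 CPM of all UMIs in 3-month replicates 1 and 2 and at 0.28 CPM or less in the other 5 libraries. Ddx3y, a gene of the Y chromosome, stood at 105.1, 98.43 and 84.43 CPM in the 12-month libraries, at 101 and 79.97 CPM in 3-month replicates 3 and 4, and at 0 in 3-month replicates 1 and 2. By these genes 3-month replicates 1 and 2 came from females and the other 5 libraries from males, so sex is not balanced between the ages. Sex-linked genes were kept out of the named genes. Without these 2 libraries, an alternative chosen after the data were seen, the counts were 267 in capillary, 12 in arterial, 177 in pericyte and 140 in erythroid sums.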

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

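Of the tests reported in this part, those on free RNA, on the library set and on endothelial RNA in pericyte sums were chosen only after the result was seen. A library was singled out where, among the 4 libraries of 3-month mice, the highest or lowest value lay further from the next than Dixon's critical ratio allows at 95%. Chance singles out about 1 in 20 groups, and 15 of 192 groups tested (7.81%) passed.

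The share of venous cells was 3.39% in 3-month replicate 2, against 6.0%, 6.05% and 6.19% in the others. In replicate 1, capillary sums held Rnaset2b at 98.5 CPM and Aplnr at 21.7 CPM, venous sums Dll4 at 10.1 CPM, pericyte sums Jam3 at 23.2 CPM and microglia Hspa1b at 1182 CPM, apart from the other 3 libraries. In replicate 2, Tmem119 stood apart at 1.17 CPM in capillary and Fos at 1654 CPM in venous sums, and in microglia Rsrp1 at 1081, Icam1 at 249.6, Maff at 1.42 and Klf6 at 903 CPM. In replicate 3, Ly6e in smooth muscle stood apart at 112 CPM and Selp in the erythroid class at 6.77 CPM, where the other 3 libraries held 0. In replicate 4, Jun in capillary sums stood apart at 1874 CPM. Microglia of replicate 2 gave 4 of these 15 values.

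The age difference differed between pericytes and capillary cells by the interaction test (edgeR, n = 7 libraries, log2 ± SE) for 10 named genes. Those with a higher fold in pericytes were Itga4 (2.35 ± 0.25), Arhgap42 (1.84 ± 0.42), Colec12 (1.36 ± 0.32), Klhl23 (1.31 ± 0.27) and Tfpi (1.26 ± 0.20). Those with a lower fold were Ccn1 (-1.52 ± 0.26), Ier3 (-1.31 ± 0.16), Junb (-1.29 ± 0.14), Ier2 (-1.28 ± 0.14) and Irgm1 (-1.22 ± 0.28). Of these, Arhgap42 and Colec12 lost their call without 12-month replicate 3 and Irgm1 without 3-month replicate 3, at log2 values down to 1.49 and 0.71 and up to -1.01 over the leave-one-out fits. In sums thinned to the smallest, none of the 10 kept its call, and Klhl23 (-2.89), Tfpi (-0.71), Ccn1 (0.84) and Irgm1 (0.68) turned. Junb, Ier2 and Ier3 stood lower in pericyte than in capillary sums at 12 months and not at 3 months: Junb at 1039 ± 219 against 2334 ± 329 CPM at 12 months and 1039 ± 127 against 1016 ± 214 CPM at 3 months.

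The pattern weighed first is the higher share of immediate early mRNA at 12 months, with Atf3 called in each of the 7 classes tested. Of these, the pericyte and erythroid sums also hold endothelial RNA. In capillary sums thinned to the smallest library the list mean stayed at 1.18 (adjusted p = 1.29e-46 by camera at the preset correlation). In the other 6 classes it stood at 0.52 to 1.28 in thinned sums, with each call kept by that test. The largest drop was in microglia, from 0.91 to 0.52. With an estimated correlation, the call in unthinned sums held in the arterial, venous and erythroid classes only. In thinned pericyte, smooth muscle and erythroid sums edgeR called no single gene, Atf3 included. Thinning keeps the expected share of each gene and equalises sums, not UMIs per cell. It therefore cannot decide on depth, which stays open. Free RNA of 1 source in all droplets is argued against by unequal excess in UMIs per cell at the 12-month depth. The class with the lowest excess reached 10.3% of the highest. In single 12-month libraries this share was 28.2%, 6.1% and 7.31%. In summed CPM the lowest class reached 23.7% of the highest, which cannot decide. Equal UMIs of free RNA give unequal CPM where cells held a mean of 1788 (microglia) to 5435 UMIs (venous) at 12 months. Excess UMIs per cell were 8.71 ± 1.75 in pericytes, 94.5 ± 61 in venous and 29.2 ± 16.5 in capillary cells (mean ± SD, n = 3). They lay closer together in capillary (29), arterial (29), smooth muscle (24.4) and microglial cells (24.1) by the means of each age, so free RNA is argued against as the whole cause only. These 2 forms followed a first one, plain UMIs per cell, which decided nothing because 12-month cells hold fewer UMIs of all genes (capillary 2110 ± 1030 against 5689 ± 1445) and so fewer of the list in each class (52.1 ± 27.5 against 62.3 ± 18.7). Age and the library set, with its handling and dissociation, cannot be told apart, since 0 libraries of either age were made in the other's set, and both stay open, age untested.

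A second pattern is the Up call of the mural ion channel list with the Down call of the barrier solute carrier list in 12-month pericyte sums. Both calls are those of camera at the preset correlation, and neither held with an estimated correlation. A candidate explanation is less endothelial RNA in those sums. The median of channels that are no markers exceeded that of the pericyte naming markers by 0.19 (0.90 against 0.71), and the median of solute carriers that are no markers differed by -0.0031 from that of the endothelial naming markers (-0.50 and -0.50). Both lie within what this explanation allows. A change in the pericytes themselves, by age or library set, stays open and was not tested apart from it.

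A further pattern is the lower clock output in 12-month capillary cells, with Dbp at -2.46, Nr1d1 at -1.11, Tef at -1.05 and Nr1d2 at -0.85. Dbp stood at -2.68 in thinned sums (adjusted p = 0.000907 by edgeR). Thinning keeps the expected share of each gene and does not equalise UMIs per cell, so it cannot decide on depth, which stays open. Another hour of the day at collection, which the labels do not give, is a candidate explanation: genes that peak opposite to Dbp had a median of 1.10, with Npas2 at 1.45, Nfil3 at 2.41, Arntl at 0.75 and Clock at -0.05. Genes in phase with Dbp (Tef, Hlf, Per3, Ciart, Usp2 and Wee1) had a median of -0.22, and against the explanation stand Usp2 and Wee1 among them, at 1.70 and 0.47. Both gene groups were picked after Dbp, Nr1d1 and Nr1d2 were seen and before their own values were. Age and library set stay open and were not told apart from it.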

How the results depend on the processing

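The fits without 3-month replicates 1 and 2 and those without the low-UMI capillary cluster were tests chosen only after the result was seen, and the others were planned. Of values for single genes and lists, direction and side of the threshold were kept in most settings. For lists, direction is that of the test. The numbers kept, and those that kept the direction only, were 603 and 3 with size factors of DESeq2, 502 and 12 with its Wald test, 594 and 12 without a filter. They were 125 and 21 with at least 50 CPM, 557 and 44 with doublets kept, 507 and 84 with no integration, 483 and 38 at resolution 1.0. They were 141 and 48 with at least 1000 genes per cell, 187 and 2 with at most 10% mitochondrial UMIs, 187 and 1 without sex-linked, mitochondrial and ribosomal genes. Between classes they were 322 and 20 at 12 months alone, 328 and 15 at 3 months alone and 267 and 76 without the library term. In the remaining settings they were 205 and 48 with the replicate number as a block, 94 and 121 in thinned sums, 5 and 69 with an estimated correlation, 9 and 65 with fry, 218 and 45 without the libraries that hold Xist and 50 and 12 without the low-UMI cluster.

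The numbers of age genes that moved by over 1.5 times were as follows, and the cause was not tested unless the setting shows it. With no filter, which tests more genes, they were capillary 1150, arterial 263, venous 666, pericyte 243, smooth muscle 156, microglia 295, erythroid 197. With at least 50 CPM, which tests fewer, they were capillary 55, arterial 8, venous 65, smooth muscle 11, erythroid 38, and the interaction gave 227. In sums thinned to the smallest, which hold fewer UMIs, they were capillary 56, arterial 13, venous 88, pericyte 0, smooth muscle 0, microglia 1, erythroid 0 and 0 for the interaction. Where edgeR gave 0 in thinned sums, genes at an unadjusted p under 0.05 numbered 24 in pericytes, 235 in smooth muscle, 77 in the erythroid class and 286 for the interaction, and no other tool was run on those sums. The Wald test gave arterial 84, pericyte 46 and 217 for the interaction. With doublets kept they were pericyte 50, smooth muscle 3, and with no integration arterial 61, pericyte 16, smooth muscle 14. At resolution 1.0 they were arterial 19, pericyte 315 and 805 for the interaction. With at least 1000 genes per cell, which also left 6 libraries for pericytes, they were pericyte 17 and 167 for the interaction. Without the libraries that hold Xist they were capillary 267, arterial 12, pericyte 177, smooth muscle 25, erythroid 140 and 164 for the interaction, and the cause was not tested. The labels do not say that the replicate numbers pair the libraries. Correlations of capillary deviations from the age means were 0.0421, 0.307 and -0.0648 between equal numbers and -0.283 to 0.197 between others. With them as a block the counts were capillary 206, microglia 53. Between classes without the library term they were 109 in arterial against capillary, 187 in venous against capillary and 152 in capillary against pericyte.

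Leaving out 1 library, with the cause of the changes not tested, gave age gene counts of 278 to 882 in capillary, 13 to 102 in arterial, 85 to 424 in venous, 9 to 293 in pericyte, 13 to 92 in smooth muscle, 70 to 136 in microglia and 37 to 143 in erythroid sums, and 196 to 393 for the interaction. In 6 of the 7 classes the highest count came without 3-month replicate 1, and in microglia without 3-month replicate 2. Lists called ranged over 9 to 18 in smooth muscle and 5 to 10 in the erythroid class. List means over the same fits ran through 0 or close to it for nuclear oxidative phosphorylation in arterial (-0.30 to 0.0518), erythroid (-0.316 to 0.0113) and pericyte sums (-0.288 to 0.0119) and the interferon response in capillary sums (0.00436 to 0.43). Differences in share, in percentage points, ranged over -0.0541 to 0.118 for T or NK cells, -0.0699 to 0.405 for choroid plexus, -2.3 to 1.53 for endothelial cells of no named segment, -0.487 to 1.59 for erythroid cells, -0.67 to 1.21 for smooth muscle, -0.0847 to 1.06 for unnamed cells and -0.54 to 1.74 for venous cells.

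Lists called were capillary 0, arterial 1, venous 1, pericyte 0, smooth muscle 0, microglia 1, erythroid 2 with an estimated correlation and capillary 3, arterial 1, venous 1, pericyte 0, smooth muscle 0, microglia 2, erythroid 2 with fry. Camera with an estimated correlation gave unadjusted p under 0.05 for 4 capillary, 3 pericyte and 6 smooth muscle lists, and fry for 6 pericyte and 8 smooth muscle lists. They were pericyte 2, microglia 7, erythroid 3 in thinned sums, venous 11, microglia 17 without a filter, smooth muscle 9 with doublets kept and arterial 11 without the libraries that hold Xist. List means that turned, where the cause was not tested, were arterial Wnt genes (0.0780), arterial solute carriers (0.18) and venous ribosomal proteins (-0.10) with no integration, and smooth muscle VEGF, angiopoietin and Notch genes (-0.10) and solute carriers (-0.39) with doublets kept. For these 2 smooth muscle lists the test alone turned with no integration, with means of 0.14 and 0.0148. Means turned beside a test that did not for smooth muscle TGF-beta and BMP genes with doublets kept (-0.0609), for sex-linked genes without a filter in pericyte (-1.56), smooth muscle (-1.99) and microglia sums (-2.22), and for pericyte mural contractile genes in thinned sums (0.49), with no integration (0.16) and with the replicate block (0.41). Leaving out 12-month libraries turned the same 3 sex-linked means, down to -2.66, and that of activated microglia genes in pericytes (-0.35 and -0.84). Leaving out 3-month replicate 1 turned that of smooth muscle ribosomal proteins (0.00415).

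Single values that turned, the cause not tested, were Ccn1 (0.84), Irgm1 (0.68), Klhl23 (-2.89) and Tfpi (-0.71) in the interaction and Dnajb1 (-0.38) in the erythroid class in thinned sums. In smooth muscle with doublets kept they were Cldn5 (-0.0324) and Flt1 (-0.00641). Between classes, venous against capillary Atp2a2 turned at resolution 1.0 (0.00699), and pericyte against smooth muscle Ccnd1 with no integration (1.67) and Cd63 at 12 months alone (0.00833). In capillary against pericyte, Icam1 (-0.60), Csf1 (-0.30), Ifi27l2a (-0.17), H2-Q7 (-0.39), Atf3 (-0.21), Jun (-0.0212) and Cd9 (-0.35) turned at resolution 1.0. With no integration Ifi27l2a (-0.43), H2-Q7 (-0.19), Atf3 (-0.29), Jag2 (-0.40) and Cd9 (-1.05) turned, of which Cd9, Ifi27l2a and Jag2 passed the threshold. Differences in share that turned were choroid plexus at resolution 1.0 (-0.0304), endothelial cells of no named segment at resolution 1.0 (-1.47), with no integration (-14.7) and with the replicate block (-0.412), smooth muscle with at most 10% mitochondrial UMIs (-0.639), unnamed cells with no integration (-0.166) and venous cells at resolution 1.0 (-0.0343).

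Median correlations between replicates at 12 and 3 months, over genes with at least 10 CPM alone, were 0.965 and 0.972 in capillary, 0.940 and 0.945 in arterial, 0.953 and 0.956 in venous, 0.670 and 0.889 in pericyte, 0.892 and 0.928 in smooth muscle, 0.863 and 0.908 in microglia and 0.821 and 0.916 in erythroid sums. With log2(CPM + 10) they were 0.981 in venous sums at 12 months, 0.955 in pericyte sums at 3 months, and 0.956 and 0.970 in smooth muscle, 0.949 and 0.964 in microglia and 0.936 and 0.964 in erythroid sums. Depth limits how many genes thinned sums can test: the smallest pericyte sum held 52143 UMIs, and thinning to it left 1094 genes. Without that library the pericyte count was 93.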

Other observations

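Some clusters entered the shares alone and no gene test. A cluster of 1301 endothelial cells led by Plvap, the protein of endothelial fenestrae, Esm1 and Igfbp3 was named to no segment. It held 469, 44 and 186 cells of the 12-month and 168, 104, 249 and 81 of the 3-month libraries. A cluster of 205 endothelial cells led by Apln, Kit and Angpt2, genes of angiogenic tip cells, held 9, 9 and 53 against 41, 34, 27 and 32 cells. Of other unnamed clusters, 441 cells were led by the platelet genes Pf4 and Ppbp (21, 139 and 91 against 38, 46, 48 and 58) and 298 by the myeloid genes Lyz2 and H2-Ab1 (129, 39 and 84 against 11, 12, 11 and 12). Another 271 cells were led by the fibroblast genes Dcn and Col3a1 (27, 20 and 18 against 40, 47, 62 and 57) and 339 by a mix of the astrocyte gene Slc1a2 and the myelin gene Mbp (5, 52 and 130 against 52, 25, 52 and 23). No test was run on these numbers of cells.

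Classes outside the gene tests took small shares: 0.793% ± 0.816 against 1.26% ± 0.233 for B cells, 0.508% ± 0.173 against 0.474% ± 0.0592 for T or NK cells and 0.568% ± 0.493 against 0.363% ± 0.266 for choroid plexus epithelium at 12 and 3 months (mean ± SD, n = 3 and n = 4). The exact permutation test gave p = 0.314, 0.771 and 0.543, the smallest possible being 0.0286. Choroid plexus markers summed to 158 ± 84.5 against 473 ± 434 CPM in capillary sums. Dbp was lower at 12 months in arterial (-2.44), venous (-2.37) and erythroid (-1.87) sums too, with adjusted p of 0.00589, 0.00358 and 0.00981 by edgeR. It did not pass in pericytes (-1.29), smooth muscle (-1.54) and microglia (-0.56), with 0.15, 0.135 and 0.568.

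Other splits of the 7 libraries into 3 and 4 were fitted in the same way, 35 splits in all with the real one, as planned. For the numbers of age genes, 1 of 35 splits, the real one, gave as many in each of the 7 classes and for the interaction. This is the smallest share that 35 splits allow. It makes chance unlikely and does not exclude it, and these results rest on the same 7 libraries. The real count and the highest of the others were 510 and 1 in capillary, 38 and 2 in arterial and 252 and 26 in venous sums. They were 85 and 27 in pericyte, 43 and 29 in smooth muscle, 108 and 27 in microglia, 61 and 22 in erythroid sums and 362 and 27 for the interaction. In pericytes the real split also gave the most lists (15 and 13, 1 split), which does not pass once the 7 list tests are adjusted together. Other splits gave as many lists or more in capillary (11 and 14, 12 of the 35 splits giving as many), arterial (7 and 16, 23 splits) and venous sums (7 and 13, 25 splits). They also did in smooth muscle (14 and 15, 2 splits), microglia (11 and 13, 5 splits) and erythroid sums (9 and 12, 11 splits). Between classes, 64 exchanges of the 2 classes within libraries were run. In each of the 4 comparisons 1 exchange, the real one, gave as many. The classes were made by clustering the same cells on expression, so mixing their names lowers the count by construction. These exchanges therefore cannot decide on chance. The counts were 255 and 125 in arterial against capillary, 336 and 245 in venous against capillary, 388 and 241 in pericyte against smooth muscle and 238 and 117 in capillary against pericyte.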
